A study of Mus musculus with 5 samples.

How the data were processed

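Basal epidermal progenitors were isolated from the back skin of control mice at postnatal day 71. Per the labels' protocols, the mice carried a K14-RFP and a K10-H2B-GFP reporter, which mark basal and suprabasal keratinocytes, and cells positive for Sca1, high for RFP and negative for GFP were sorted. Libraries were made from 5 ng of DNA and sequenced as single reads of 75 nt. There were 2 libraries for H2AK119ub, 2 for H3K27me3 and 1 input library.

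The authors deposited 1 list of regions per mark, with the columns chromosome, start and end per the file headers. A region's height, score, p-value and replicate were not analysed here. Bowtie2 2.3.3.1, SAMtools 1.9 and the genome build mm10 are named per the submitters' processing notes, without their role or order. The peak caller, its thresholds, the use of the input and any pooling of the 2 libraries per mark are not given in the sources used here. These choices set the number and width of regions, so the lists' sizes cannot be read as amounts of either mark. The number of reads per library is unknown, and no interval for depth or limit of detection is given. A gene without a called region may carry the mark below the unknown threshold.

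Starts were read as counted from 0 and converted to positions counted from 1. The files' header line leaves this uncertain by 1 bp. The lists held regions on 19 autosomes and X. Genes came from a RefSeq table of GRCm38.p6, the same build as mm10, with 21631 protein-coding and 49554 annotated genes on these chromosomes. The table gives the first and last position of each gene without strand, exons or transcript starts, so the planned window around the 5' end was replaced by a window of 1 kb around either annotated end. Each gene was classed as having both marks, H2AK119ub alone, H3K27me3 alone or neither. A region inside a gene and away from both ends did not count, so an absent mark means absent at the ends. Transcript starts inside long genes were not examined. The agouti gene, listed there under its classical symbol, is named Asip. Coverage is given over the span from the first to the last gene or region of each chromosome, 2612 Mb in all.

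Region lists were compared by overlap of at least 1 bp. The expected share came from 100000 circular shifts of the other list within each chromosome, which keep widths and clustering, with a one-sided p for excess. Widths of shared and unshared regions were compared by a two-sided permutation test of the difference in medians with 100000 resamples. The association of the marks over genes was described by the odds ratio of the 2 by 2 table of genes, whose two-sided Fisher's exact p was too small for the software to represent and is not given. A circular-shift test over genes with 10000 shifts was added after the data had been seen, since neighbouring genes share regions. There were 20 gene lists, 15 of them lists of symbols and 5 of them families defined by name patterns. They were fixed before the data were examined, and cover keratinocyte-derived pigmentation factors, melanocyte, Merkel, fibroblast, immune and endothelial cells, Hox clusters, transcription factors of non-epidermal lineages, basal and suprabasal epidermis, hair follicle, cell cycle inhibitors, signalling ligands, Polycomb subunits, housekeeping genes, cytosolic ribosomal proteins, olfactory receptors, keratins, protocadherins and solute carriers. Of 410 symbols, 3 had no row of their own, and 2 of these, Tbxt and Loricrin, are other names of genes already in the lists. Each list was set against all other protein-coding genes by a two-sided Fisher's exact test, adjusted by the Benjamini-Hochberg method over 40 tests (20 lists and 2 marks), with a threshold of 0.05. The share of a list's H2AK119ub genes with H3K27me3 was tested in the same way over 20 lists. Genes were the units of these tests, so the p-values describe the 2 lists and not variation between mice. Shares carry 95% Clopper-Pearson intervals where given.

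Named genes followed a rule set before the data were examined. It took every marked gene of the pigmentation, melanocyte, Merkel and cell cycle lists (and the unmarked genes where fewer than 10), up to 4 genes per class with the widest region for the other symbol lists, and the 10 genes with the widest region in each class over all genes, with 1 gene per region, the one with an end nearest its centre. Genes with neither mark have no width to rank, so where these were more than 4, as in the suprabasal and Polycomb lists, the ones named were chosen after the values had been seen. Some genes that the rule takes are not reported here. For genes with both marks the width of the H3K27me3 region was used. Region widths in the text are those of the widest region within 1 kb of an end.

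The overlap and list tests were first tested on simulated data. Counting overlaps over shifts differed by 0 regions from a direct recount over 10 shifts. Of 40 region lists made by shifting the H2AK119ub list, 2 were called against H3K27me3 at an unadjusted 0.05 threshold. The test uses the same kind of shift, so this rate checks the computation. It cannot show whether shifted lists are a fitting comparison for real ones. Of 200 simulated lists of 25 genes with a planted odds ratio of 4, drawn among 21631 genes, 190 were recovered, and of 200 without an effect, 4 were called. Genes were marked independently of each other there, at the overall rate of H3K27me3. These rates therefore do not cover lists whose genes share regions, or the higher rate of H2AK119ub.

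Alternatives planned before the data were examined were an overlap of 50% of a region or a distance of 1 kb, the widest 50% of each list, equal numbers of regions, merging of regions within 3 kb, random placement, windows of 0 bp and 5 kb, all annotated genes, autosomes alone for the overlap, and loci of 100 kb. For loci, neighbouring genes of a list within 100 kb were joined, and so, separately, were the other genes. A locus counted as marked when at least 50% of its genes were. Loci of other genes can hold many genes, so the 2 sides of this comparison differ in kind. The autosomes alone for the gene results, a region anywhere in the gene body, and a mark at both gene ends were added after the data had been seen. Alternatives and tests that need strand, transcript starts, DNA sequence (CpG-rich promoters), region scores or values per replicate were not run. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.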

Results

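Chromatin immunoprecipitation and sequencing was done on basal progenitor cells of the epidermis, sorted from the back skin of control mice at postnatal day 71. One antibody recognised H2AK119ub, monoubiquitinated histone H2A, which is the product of Polycomb repressive complex 1 (PRC1). The other recognised H3K27me3, histone H3 trimethylated on a lysine of its tail, which is the product of Polycomb repressive complex 2 (PRC2). There were 2 libraries per antibody and 1 input library. The data were 1 list of called regions per mark, with chromosome, start and end and no height, score or replicate column. The read depth of each library and the spread between replicates are therefore unknown, and every statement below describes these 2 lists. The title of the series concerns the role of PRC1 and PRC2 in skin pigmentation, and the lists address where the marks lie, how far they coincide and which genes carry them.

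Called H2AK119ub regions covered more of the autosomes than called H3K27me3 regions did, and the reverse held on the X chromosome. The H2AK119ub list held 33155 regions covering 487 Mb, or 18.7% of the span of the chromosomes, and the H3K27me3 list held 15102 regions covering 250.3 Mb, or 9.58%. H2AK119ub covered 17.5% of the autosomes and 34.6% of X, whereas H3K27me3 covered 6.15% of the autosomes and 58.7% of X. Among autosomes, chromosome 11 had the highest coverage and chromosome 3 the lowest for both marks, at 30.9% and 10.9% for H2AK119ub and 10.1% and 3.20% for H3K27me3. Region width was similar for both marks on the autosomes, with medians of 8.09 kb for H2AK119ub and 7.69 kb for H3K27me3. On X the median H3K27me3 region was 22.1 kb wide, against 8.17 kb for H2AK119ub, and 256 of the 306 H3K27me3 regions of 100 kb or more lay there. The widest H3K27me3 region spanned 1114 kb of X from 52361676 to 53475719 and contained Phf6, a chromatin-associated zinc finger gene, and Hprt, a purine salvage gene. No test was made of these values, because a single list per mark gives no replicate error. The unknown calling thresholds set the covered length of each list, so the coverages do not compare amounts of the marks. The labels do not state the sex of the mice.

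**Figure D1:**
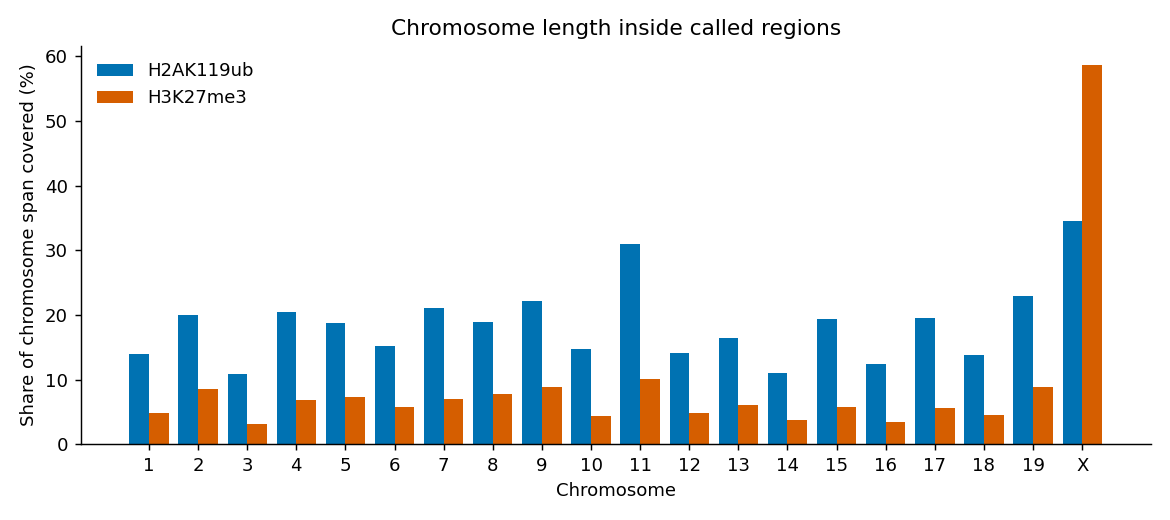
Share of each chromosome's span (vertical axis, in percent) inside called H2AK119ub regions (blue bars) and H3K27me3 regions (orange bars), for the 19 autosomes and X (horizontal axis). H3K27me3 covers 58.7% of X and at most 10.1% of an autosome, while H2AK119ub covers 34.6% of X and at most 30.9% of an autosome.

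Most H3K27me3 regions lay in H2AK119ub chromatin, while most H2AK119ub regions lacked H3K27me3. Of the 15102 H3K27me3 regions, 10386 (68.8%) shared at least 1 bp with an H2AK119ub region. Of the 33155 H2AK119ub regions, 11211 (33.8%) shared at least 1 bp with an H3K27me3 region. The lists differ in size, and with equal numbers of regions, the widest kept, the shares were 53.0% and 45.3%. The contrast between the marks was thus much smaller at equal list size. The shared sequence amounted to 157.9 Mb, which was 63.1% of the H3K27me3 length and 32.4% of the H2AK119ub length. When the other list was shifted around each chromosome, the mean share was 29.8% for H3K27me3 regions and 16.5% for H2AK119ub regions. The highest shares among 100000 shifts were 36.4% and 20.8%, so that the one-sided permutation p was 1e-05 in both directions, the smallest these shifts can give. Shifts do not keep the place of regions relative to genes. Part of the excess may therefore come from both marks being frequent at gene ends. The X chromosome differed from the autosomes in the direction of the overlap. On X, 98.3% of H2AK119ub regions overlapped H3K27me3 and 53.7% of H3K27me3 regions overlapped H2AK119ub, against 27.2% and 71.3% on the autosomes. The difference between X and the autosomes was not tested.

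Shared regions were wider than unshared ones for both marks. H2AK119ub regions that met H3K27me3 had a median width of 12.1 kb, and those that did not had a median of 6.76 kb. H3K27me3 regions that met H2AK119ub had a median width of 10.02 kb, and those that did not had a median of 6.21 kb. The two-sided permutation p was 1e-05 for each mark with 100000 resamples, the smallest these can give. A wide region meets the other list more easily by chance, and neighbouring regions are not independent, so these p-values describe the lists alone.

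Both marks were found at the ends of protein-coding genes more often than shifted windows gave. Within 1 kb of an annotated gene end lay 10683 of the 33155 H2AK119ub regions (32.2%, against a mean of 15.8% for shifted windows). For H3K27me3 the count was 4708 of 15102 (31.2%, against 16.2%). The one-sided permutation p was 1e-05 for both, the smallest that 100000 shifts can give. A further 29.4% of H2AK119ub and 21.9% of H3K27me3 regions lay inside a gene away from its ends, and 38.3% and 46.9% lay outside protein-coding genes.

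Of 21631 protein-coding genes, 4561 carried both marks within 1 kb of an annotated end, 7782 carried H2AK119ub alone, 775 carried H3K27me3 alone and 8513 carried neither. H2AK119ub was thus present at 57.1% of genes and H3K27me3 at 24.7%. Among the genes with H3K27me3, 85.5% also had H2AK119ub, and among the genes with H2AK119ub, 37.0% also had H3K27me3. The odds ratio between the marks over genes was 6.44 (2.69 on the log2 scale). When the H3K27me3 list was shifted within chromosomes, the log2 odds ratio averaged 0.30 and reached 0.87 at most, with a one-sided permutation p of 0.0001, the smallest that 10000 shifts can give. The shift also moved H3K27me3 away from gene ends, and shifted lists marked 2953 genes on average, against 5336 observed. It therefore cannot separate the association from a common preference of the marks for gene-rich sequence. On the autosomes the observed odds ratio was 6.07. On X, 673 of 966 genes had both marks, 90 had H3K27me3 alone, 197 had neither and 6 had H2AK119ub alone. The gene table gives no strand, so a mark at a gene may lie at its 5' or its 3' end, and 40.2% of the genes with H2AK119ub and 58.4% of those with H3K27me3 were marked at 1 end.

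The widest H3K27me3 regions at genes with both marks lay on X, at Phf6 (1114 kb), Hcfc1 (980 kb), Pja1 (782 kb), Bcor (753 kb), Frmpd3 (683 kb), AA414768 (582 kb), Arhgef6 (531 kb), Il13ra1 (523 kb), Efhc2 (507 kb) and Rps4x (495 kb). Bcor encodes a corepressor found in a variant form of PRC1. The widest such regions on the autosomes, a ranking made after the values had been seen, were at Foxf1 (300.2 kb on chromosome 8), Pax2 (281 kb on chromosome 19), Foxb1 (204 kb on chromosome 9), Tbx4 (199 kb on chromosome 11), Gm5820 (179 kb on chromosome 18) and Hoxd9 (178 kb on chromosome 2), followed by Dmrt3, Barhl2, Hoxc13 and Clec4f. Genes with H2AK119ub alone were led by Tle3, a Groucho family corepressor, in a 582 kb region of chromosome 9 from 61149570 to 61731348. Next came Gins2 (389 kb), Pdk2 (371 kb), Hes1 (348 kb), Slc25a33 (332 kb), Ackr3 (321 kb), Prkar1b (309 kb), Cbx2 (301 kb), Rxra (292 kb) and Ncoa3 (291 kb). Hes1 is a target of Notch signalling, Cbx2 encodes a chromodomain subunit of PRC1 and Rxra a retinoid receptor. The 10 widest regions at genes with H3K27me3 alone all lay on X, at Gemin8 (227 kb), Siah1b (187 kb), Hdx (166 kb), H2al1a (147 kb), Frmpd4 (134 kb), Gm52417 (127 kb), Cfap47 (124 kb), Amelx (109 kb), 1700020N15Rik (109 kb) and Cdr1 (97.8 kb).

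Genes listed beforehand as keratinocyte-derived pigmentation factors, the group closest to the series' title, were marked more often than other genes. Which skin cells express them was not analysed here. An excess of H3K27me3 was not particular to this list. It was also found in ligand genes (81.8%) and dermal fibroblast genes (66.7%), but not in basal epidermal genes (19.2%). Of the 23 pigmentation factor genes, 20 (87.0%) carried H2AK119ub, against 57.0% of other genes. H3K27me3 was carried by 13 (56.5%), against 24.6% of other genes. Both marks were present at 12 of them. Kitl, the ligand of the melanoblast receptor Kit, had a 35.7 kb H2AK119ub region on chromosome 10 from 100003512 to 100039205, across its lower-coordinate end at 100015615, and a 9.50 kb H3K27me3 region from 100006101 to 100015603, which stops just outside that end. A second H3K27me3 region of 2.60 kb lies inside the gene, from 100016976 to 100019571. Asip, the agouti signal that switches melanocytes to yellow pigment, had a 47.9 kb H3K27me3 region and a 22.5 kb H2AK119ub region on chromosome 2. Pomc, the precursor of melanocyte-stimulating hormone, had a 14.0 kb H3K27me3 and a 5.11 kb H2AK119ub region. Both marks were also found at Bmp4, Bmp6, Cxcl12, Dkk1, Fgf2, Igf1, Sfrp2 and Wnt7a, among which H3K27me3 was widest at Bmp6 (26.6 kb) and narrowest at Bmp4 (1.86 kb). H2AK119ub alone was found at 8 genes. These were the endothelin genes Edn1 (22.5 kb) and Edn2 (122 kb), the cytokine genes Csf2 (76.96 kb), Lif (70.8 kb), Tnf (23.5 kb), Il1a (12.5 kb) and Il6 (9.96 kb), and the transcription factor gene Foxn1 (58.5 kb). Edn3 had H3K27me3 alone, in a region of 2.76 kb, and Hgf and Nrg1 had neither mark at their ends. By two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 40 tests of 20 gene lists and 2 marks, the adjusted p was 0.00549 for H2AK119ub (95% Clopper-Pearson interval of the share 66.4 to 97.2%) and 0.00227 for H3K27me3 (34.5 to 76.8%). Among the genes of this group with H2AK119ub, 60% had H3K27me3, against 36.9% of other H2AK119ub genes (adjusted p = 0.0692 over the 20 lists, Fisher's exact test). The adjusted p of this test became 0.0294 on the autosomes alone, 0.0732 with a window of 5 kb and 0.347 with a window of 0 bp. When a mark was required at both ends of a gene, 3 of the 23 genes had H3K27me3 and the adjusted p was 0.854.

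**Figure D2:**
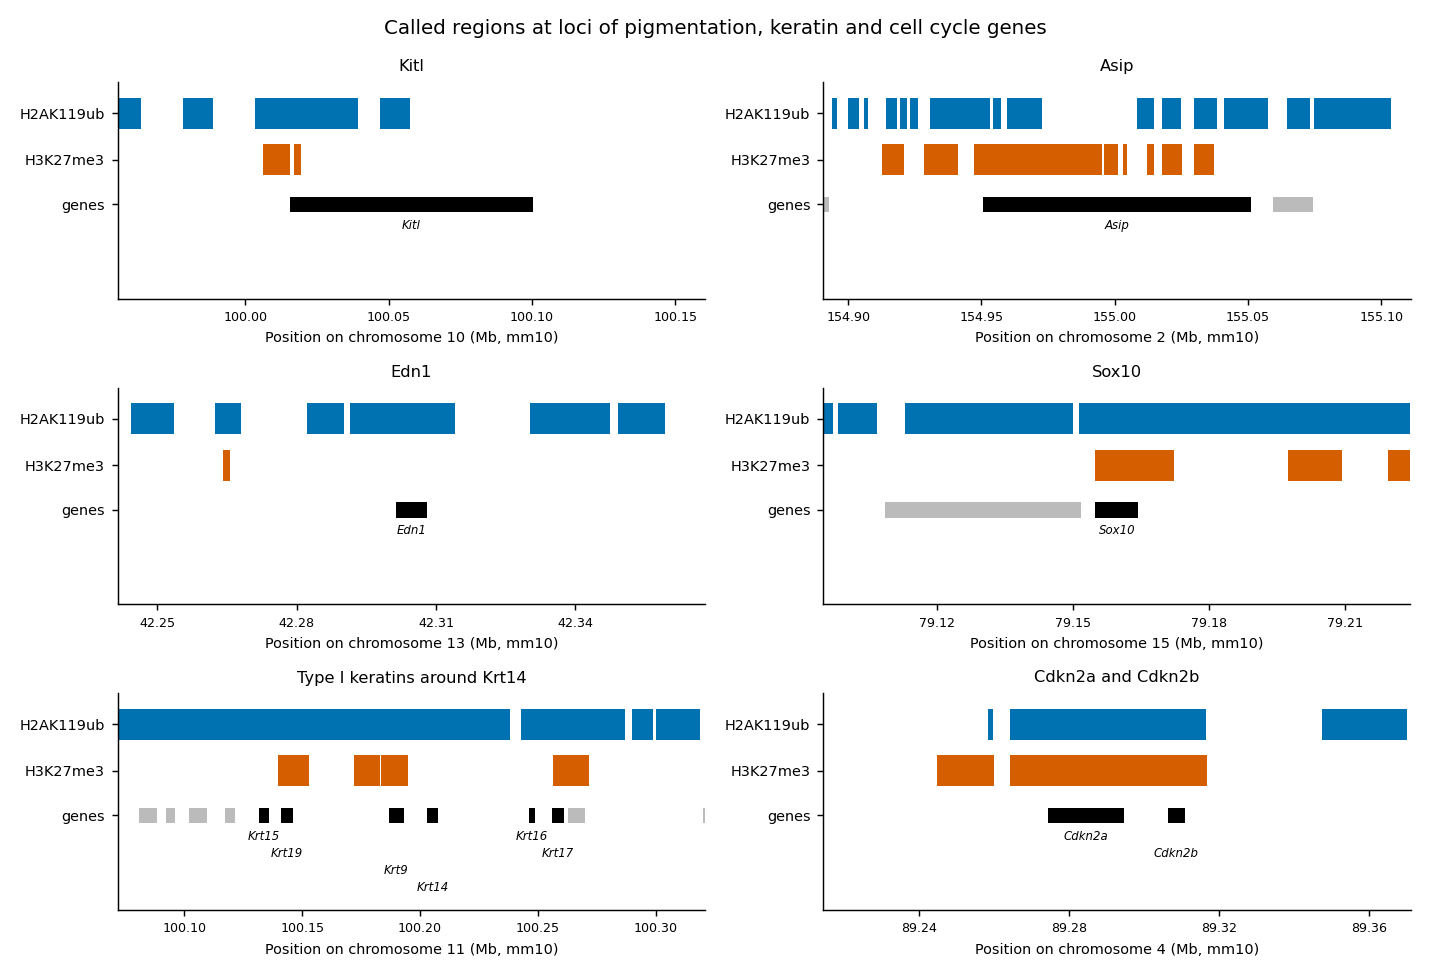
Called regions of H2AK119ub (blue) and H3K27me3 (orange) and protein-coding genes (black where named, grey otherwise) along the chromosome (horizontal axis, position in Mb of mm10) at Kitl, Asip, Edn1, Sox10, the type I keratins around Krt14, and Cdkn2a with Cdkn2b. Kitl has both marks within 1 kb of 1 end, Edn1 lies in a 22.5 kb H2AK119ub region without H3K27me3, and a single H3K27me3 region of 52.4 kb coincides with an H2AK119ub region over Cdkn2a and Cdkn2b.

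Of 22 genes of the melanocyte lineage, 14 (63.6%) carried H2AK119ub, against 57.1% of other genes, and 11 (50%) carried H3K27me3, against 24.6%. Sox10, which specifies neural crest derivatives, had an 80.5 kb H2AK119ub region and a 17.5 kb H3K27me3 region on chromosome 15. Pax3 had 73.9 kb of H2AK119ub and 146 kb of H3K27me3, and Foxd3 had 36.1 kb and 42.5 kb. Kit had regions of 1.30 kb and 9.83 kb. Mc1r, Mcam, Slc45a2, Sox5 and the X-linked gene Gpr143 also had both marks. Mitf, the transcription factor that drives pigment genes, had a 5.95 kb H2AK119ub region at 1 end and no H3K27me3 at either. Dct (12.9 kb, at 1 end) and Tfap2b (19.98 kb) and Trpm1 (22.5 kb), each at both ends, also had H2AK119ub alone. Ednrb had H3K27me3 alone (4.50 kb). Tyr, Tyrp1, Pmel, Mlana, Oca2, Erbb3 and Snai2 had neither mark at their ends. The adjusted p was 0.722 for H2AK119ub and 0.0182 for H3K27me3 by the same Fisher's exact test. The H3K27me3 call of the exact test was lost with a window of 5 kb (adjusted p = 0.0867) and when genes within 100 kb were counted as 1 locus (adjusted p = 0.0843). Of the H2AK119ub genes in this group 71.4% had H3K27me3 (adjusted p = 0.0242, Fisher's exact test), a call lost in 4 alternative settings.

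Merkel cell genes were marked throughout. All 20 genes of this mechanosensory lineage carried H3K27me3, against 24.6% of other genes, and 18 also carried H2AK119ub. Sox2 had 61.4 kb of H3K27me3 and 47.6 kb of H2AK119ub, Isl1 had 33.8 kb and 33.2 kb, and Atoh1, the factor required for Merkel cell formation, had 15.2 kb and 9.46 kb. The neighbouring simple-epithelium keratin genes Krt8 and Krt18 lay in one 82.3 kb H3K27me3 region and one 77.6 kb H2AK119ub region on chromosome 15. Gfi1 (63.4 kb), Pou4f3 (48.9 kb), Insm1 (41.1 kb), Cck (39.0 kb), Prox1 (29.2 kb), Lhx3 (27.8 kb), Ncam1 (23.7 kb), Krt20 (23.6 kb), Nrcam (16.9 kb), Tubb3 (9.17 kb), Piezo2 (9 kb) and the X-linked Syp (102 kb) carried H3K27me3 regions of the widths given, together with H2AK119ub. Tubb3 shared its regions of both marks with the neighbouring gene Mc1r of the melanocyte list. Tenm2 (13.6 kb) and Rab3c (6.65 kb) had H3K27me3 alone. The adjusted p was 4.52e-12 for H3K27me3 (95% interval of the share 83.2 to 100%) and 0.00494 for H2AK119ub, by the same Fisher's exact test. Each of the 18 H2AK119ub genes had H3K27me3, against 36.9% of other H2AK119ub genes (adjusted p = 1.08e-07, Fisher's exact test).

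The Hox clusters, which encode body-axis transcription factors, lay within H2AK119ub chromatin, and H3K27me3 stopped inside 3 of the 4 clusters. All 39 Hox genes had H2AK119ub and 29 had H3K27me3. The Hoxd cluster was covered by a single 178 kb H3K27me3 region on chromosome 2 from 74612602 to 74790673. In the Hoxa cluster a 124 kb H3K27me3 region on chromosome 6 began at 52210968, over the genes from Hoxa7 to Hoxa13, and Hoxa2, Hoxa4, Hoxa5 and Hoxa6 had H2AK119ub alone. Hoxa3 counted as having both marks because the far end of its long annotated body reaches that region. In the Hoxb cluster H3K27me3 ran from 96142881 to 96302179 on chromosome 11 in 2 regions, separated by a short gap, of 142 kb and 16.9 kb over Hoxb6 to Hoxb13. Hoxb2 to Hoxb5 had H2AK119ub alone, within a region of 275 kb, and Hoxb1 had a separate 5.31 kb H3K27me3 region. In the Hoxc cluster a 159.5 kb H3K27me3 region on chromosome 15 reached from beyond Hoxc13 to the near end of Hoxc6, Hoxc5 had H2AK119ub alone, and Hoxc4 had a separate 12.5 kb region. The Hox genes named beyond 4 per class were chosen after the values had been seen. The adjusted p was 1.50e-09 for H2AK119ub and 3.77e-10 for H3K27me3 by the same Fisher's exact test. Genes of a cluster share regions and are not independent, and the 4 loci are too few for a test by locus.

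**Figure D3:**
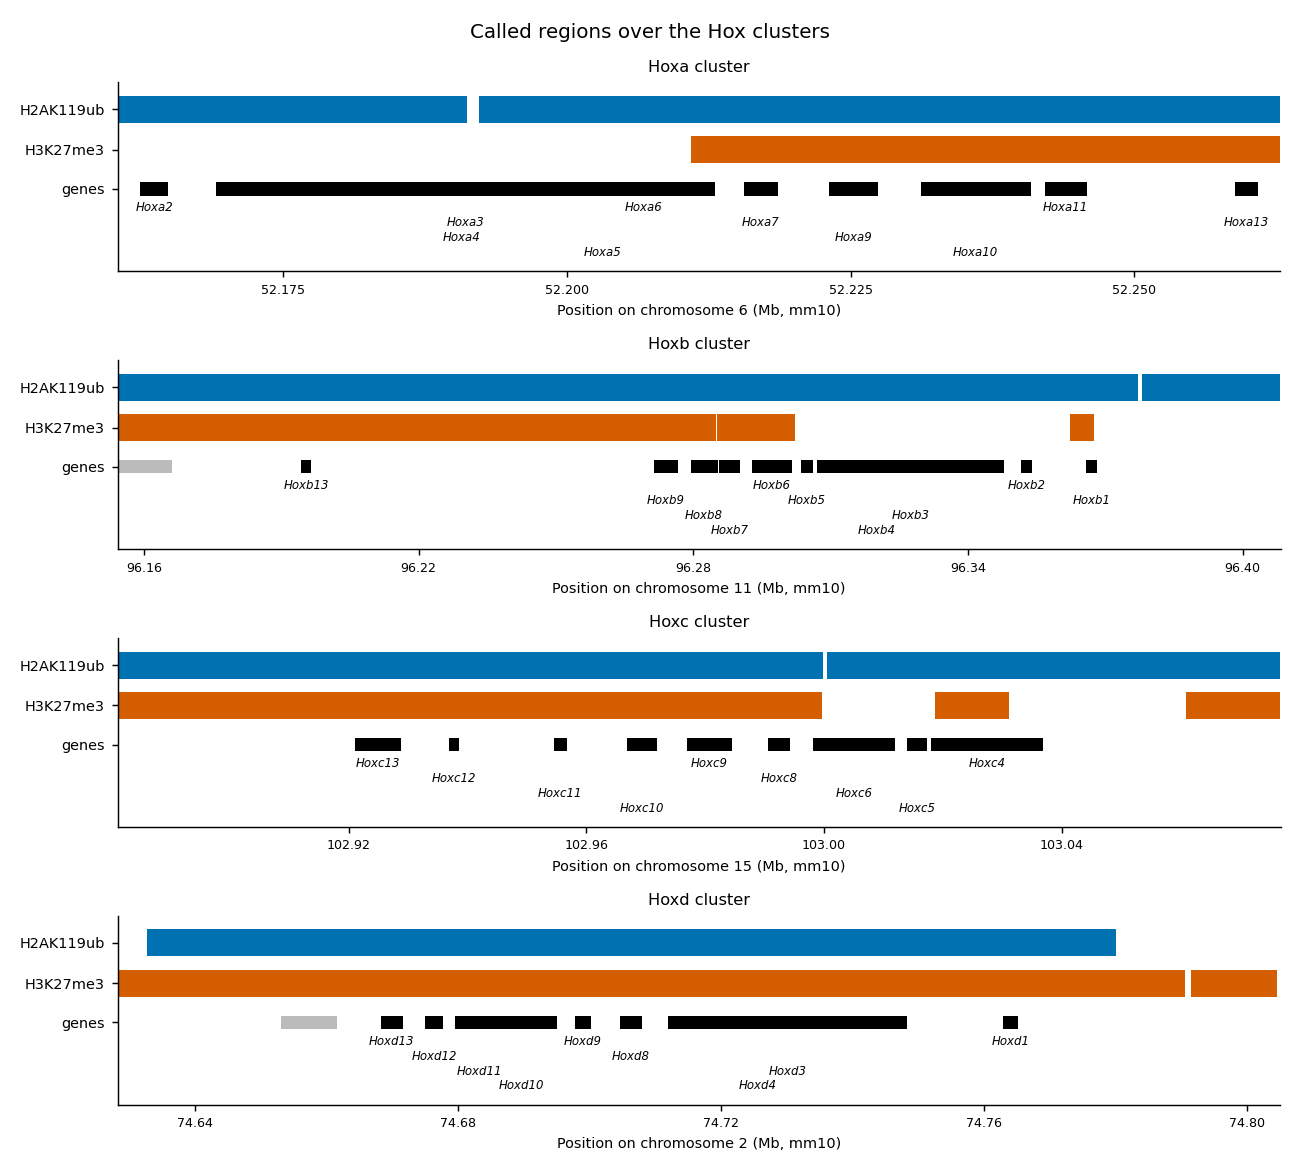
Called regions of H2AK119ub (blue) and H3K27me3 (orange) and protein-coding genes (black for Hox genes, grey otherwise, with overlapping genes drawn on 1 line) along the Hox clusters, the Hoxa cluster from Hoxa2 on (horizontal axis, position in Mb of mm10). H2AK119ub extends over the genes shown, while H3K27me3 is absent from Hoxa2 to Hoxa6 apart from the far end of Hoxa3, and from Hoxb2 to Hoxb5.

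Transcription factors that specify other lineages were marked almost without exception. Of 49 genes for neural, mesodermal and endodermal regulators, 48 carried both marks, and Myf5, a muscle determination factor, carried neither. The widest H3K27me3 regions were at Pax2 (281 kb), En2 (125 kb), Evx1 (124 kb) and Six3 (122 kb). The region at Evx1 is the one that lies over Hoxa7 to Hoxa13, so it counts in both lists. The adjusted p was 2.81e-27 for H3K27me3 and 2.24e-10 for H2AK119ub by the same Fisher's exact test. Genes for Wnt, Bmp, Fgf and Hedgehog ligands and antagonists followed, with H2AK119ub at 39 of 44 and H3K27me3 at 36 of 44 (adjusted p = 2.72e-05 and 2.40e-14, Fisher's exact test). Among the 33 with both marks, H3K27me3 was widest at Fgf3 (50.8 kb), Gdf6 (49.7 kb), Ihh (44.0 kb) and Sfrp5 (40.2 kb). H2AK119ub alone was found at 6 genes, led by Bmp7 (216 kb), Wnt4 (189 kb), Wnt6 and Wnt10a (73.6 kb, shared). Sfrp4, Fgf10 and Dkk2 had H3K27me3 alone, and Bmp5 and Dkk4 had neither mark. 

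Genes of the basal epidermis, the compartment from which the cells were sorted, carried H2AK119ub more often than other genes and were not enriched for H3K27me3. Of 26 genes, 22 (84.6%) had H2AK119ub, against 57.0% of other genes, and 5 (19.2%) had H3K27me3, against 24.7%. Krt14 and Krt15, keratins of basal cells, lay in the same 202 kb H2AK119ub region on chromosome 11, Itgb4 and Lamb3, components of the anchorage to the basement membrane, had regions of 83.6 kb and 75.3 kb, and all 4 had no H3K27me3 at their ends. Krt5, the partner of Krt14, was in the same class with a region of 75.0 kb, and is named after its value was seen. Both marks were found at 5 genes, led by Dst (19.4 kb of H3K27me3), Tfap2a (16.5 kb), Tfap2c (8.87 kb) and Itga3 (7.33 kb). Trp63, the master regulator of stratified epithelia, had neither mark at its ends, and neither did Klf5, Sfn and Dsp. The adjusted p was 0.00804 for H2AK119ub and 0.722 for H3K27me3 by the same Fisher's exact test. The share of the H2AK119ub genes that also had H3K27me3, 22.7%, was not separated from the 37.0% of other H2AK119ub genes (adjusted p = 0.254, Fisher's exact test).

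Suprabasal differentiation genes had H2AK119ub at 19 of 26 (73.1%) and H3K27me3 at 4 of 26 (15.4%), neither of which passed the test (adjusted p = 0.143 and 0.429, Fisher's exact test). Krt1, Krt2 and Krt77 lay in a 137 kb H2AK119ub region without H3K27me3 at their ends, and Grhl3, a regulator of barrier formation, had a region of the same rounded width. Krt10 (9.57 kb), Prdm1 (8.92 kb), Cnfn (7.02 kb) and Lor (4.14 kb) had H3K27me3 together with H2AK119ub. Neither mark was found at 7 genes, among them the cornified envelope genes Flg, Hrnr, Rptn and Sprr1b. The H2AK119ub difference passed the exact test with a window of 0 bp (adjusted p = 0.0258), with a mark required at both ends (0.00328) and by locus (0.0275). Across the 49 keratin genes, 48 had H2AK119ub and 25 had H3K27me3 (adjusted p = 2.24e-10 and 0.000195, Fisher's exact test), and Krt40, named after its value was seen, had neither. Keratin genes sit in 2 clusters and share regions, which the test ignores.

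Hair follicle genes carried each mark more often than other genes. All 27 genes had H2AK119ub and 22 (81.5%) had H3K27me3. The widest H3K27me3 regions were at Lhx2 (135 kb) and Sox9 (61.8 kb), regulators of hair follicle stem cells, and at Foxe1 (68.1 kb) and Tbx1 (64.6 kb). Krt35 (202 kb), Krt79 (137 kb), Runx1 (78.8 kb) and Krt71 (75.0 kb) led the 5 genes with H2AK119ub alone. The regions of Krt35, Krt79 and Krt71 are those already given for Krt14, Krt1 and Krt5 of the epidermal lists. These lists are therefore not independent, which the test ignores. The adjusted p was 1.04e-06 for H2AK119ub and 2.89e-09 for H3K27me3 by the same Fisher's exact test. Their share of H2AK119ub genes with H3K27me3, 81.5%, was above the 36.9% of other H2AK119ub genes (adjusted p = 1.10e-05, Fisher's exact test).

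Genes of other skin cell types carried H3K27me3 more often than other genes. In dermal fibroblast genes H3K27me3 was found at 14 of 21 (66.7%, adjusted p = 0.000153) and H2AK119ub at 16 (76.2%, adjusted p = 0.106), by the same Fisher's exact test. Tbx15 (61.97 kb), En1 (56.1 kb), Crabp1 (38.3 kb) and Pdgfra (38.0 kb) had the widest H3K27me3 regions, and the collagen gene Col6a1 had H2AK119ub alone (31.1 kb). Mfap5 and Col1a2 had H3K27me3 alone, and Col3a1, Fap and Lum had neither mark. In immune cell genes H3K27me3 was found at 10 of 21 (47.6%, adjusted p = 0.0329) and H2AK119ub at 17 (81.0%, adjusted p = 0.0413), by the same exact test. Cd207, the Langerhans cell gene for langerin, had the widest H3K27me3 region (158 kb), followed by H2-Eb1 (40.5 kb), H2-Ab1 (21.6 kb) and Cd3d (20.7 kb), and Rac2, Mpeg1, Spi1 and Csf1r led those with H2AK119ub alone. In endothelial genes H3K27me3 was found at 9 of 17 (52.9%, adjusted p = 0.0310) and H2AK119ub at 14 (82.4%, adjusted p = 0.0677), again by the exact test. Esam (62.9 kb), Tal1 (41.1 kb), Sox17 (29.5 kb) and Flt1 (28.6 kb) had the widest H3K27me3 regions, and Egfl7, Eng, Pecam1 and Plvap led those with H2AK119ub alone. By locus the immune and endothelial H3K27me3 calls of the exact test were lost (adjusted p = 0.520 and 0.0843), and with a mark required at both ends the fibroblast and immune calls were lost (0.0915 and 0.379). The immune H3K27me3 call was also lost with a window of 0 bp (0.248), and the immune H2AK119ub call was lost with a window of 5 kb (0.0546), with equal numbers of regions (0.159) and by locus (0.0843), all by the exact test. In H2AK119ub, endothelial genes passed the exact test in 6 of 8 alternative settings (adjusted p from 0.00707 to 0.0409). Fibroblast genes passed for this mark only with a window of 0 bp (0.0242) and by locus (0.0382). With a mark required at both ends, the fibroblast difference in H2AK119ub turned to -10.3 points (5 of 21, adjusted p = 0.506, exact test).

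Among 11 cell cycle inhibitor genes, both marks were found at Cdkn2a, Cdkn2b and Cdkn1c. Cdkn2a and Cdkn2b, which encode inhibitors of cyclin-dependent kinases 4 and 6, shared a 52.4 kb H3K27me3 region on chromosome 4 from 89264283 to 89316666 and a 52.3 kb H2AK119ub region from 89264358 to 89316629. Cdkn1c had 49.6 kb of H3K27me3 and 63.3 kb of H2AK119ub. Cdkn1a (52.9 kb), Rb1 (16.9 kb), Cdkn2c (4.81 kb), Cdkn1b (4.63 kb), Rbl1 (4.42 kb) and Cdkn3 (3.68 kb) had H2AK119ub alone, and Cdkn2d and Rbl2 had neither mark. H2AK119ub was found at 9 of the 11 (81.8%, against 57.0% of other genes) and H3K27me3 at 3 (27.3%, against 24.7%). No difference was detected with 11 genes (adjusted p = 0.158 and 0.757, Fisher's exact test).

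**Figure D4:**
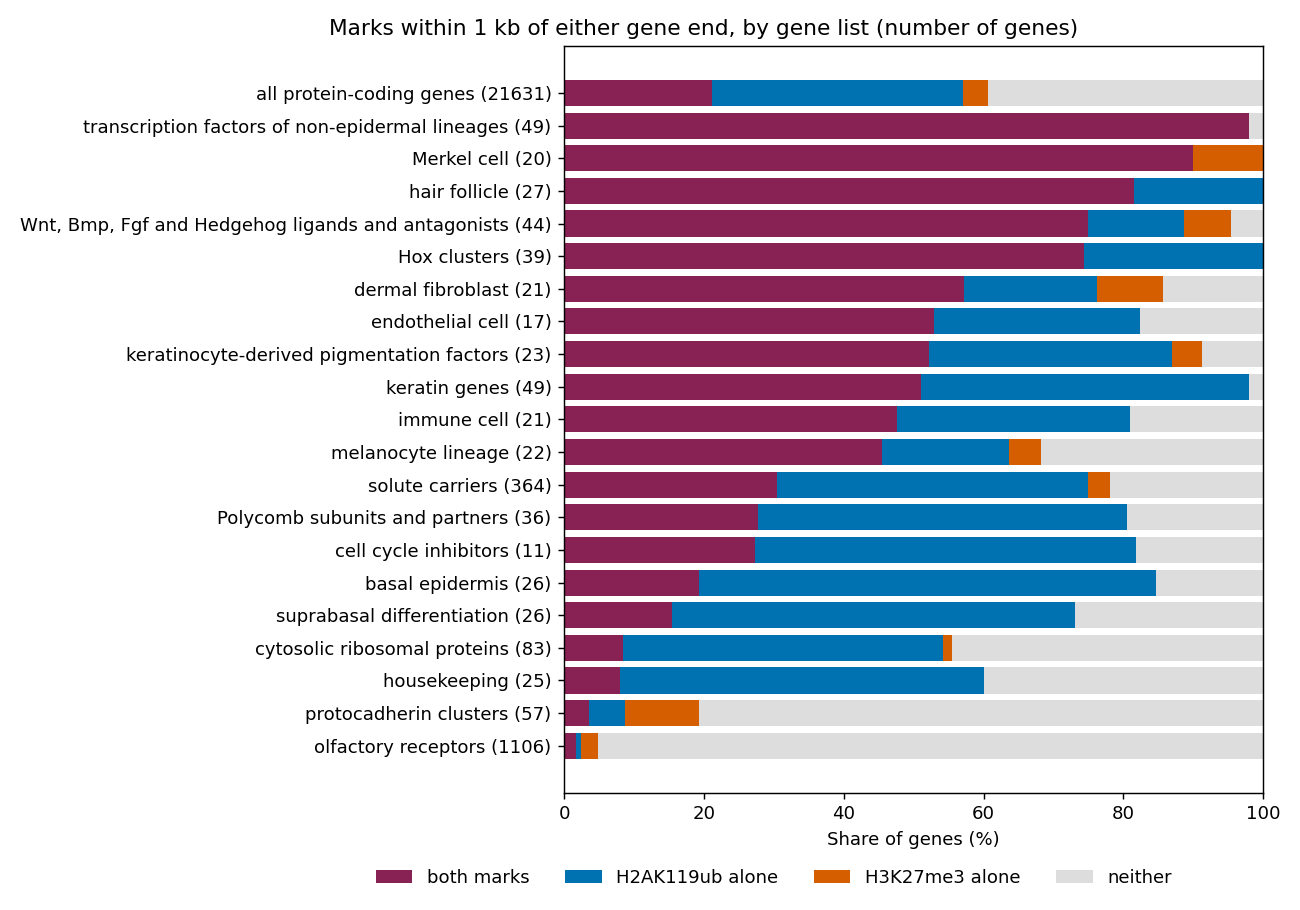
Share of genes (horizontal axis, in percent) with both marks, H2AK119ub alone, H3K27me3 alone or neither within 1 kb of either annotated end, for each of 20 gene lists and for all protein-coding genes (vertical axis, number of genes in parentheses). Of the transcription factors of non-epidermal lineages 48 of 49 have both marks, and of the basal epidermal genes 17 of 26 have H2AK119ub alone.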

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

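No paired analysis was possible because each mark is given as 1 list without values per replicate, and leaving out a replicate was impossible for the same reason. Of 504 values recomputed under an alternative, 449 kept their direction and their side of the threshold. Direction and side were kept by each value of the overlap of the lists (53.0 to 71.3% of H3K27me3 and 24.8 to 45.3% of H2AK119ub regions). The same held for the share of regions at gene ends, the widths and the association of the marks over genes. The other 55 values follow, as gene counts or as the difference in percentage points between a list and other genes, with the adjusted p where a call was lost or gained. Differences that turned direction without passing in either setting are not among them. The autosomes alone for gene results, the gene body and the both-ends rule were chosen after the data had been seen. Except where the construction is named, the cause was not tested. Tests by locus gave no value for Hox, keratin and protocadherin genes, which form fewer than 5 loci. Alternatives with all transcript starts, CpG-rich promoters or region scores were not run. Unknown depth and an unknown calling threshold limit every absence of a mark.

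With the widest 50% of each list, which holds fewer regions, 2978 genes had both marks instead of 4561. Endothelial genes then passed for H2AK119ub (31.1 points, 0.0211) and Polycomb genes no longer did (15.7 points, 0.0909). With equal numbers of regions, which removes H2AK119ub regions, 1494 genes had H3K27me3 alone instead of 775. Endothelial genes passed for H2AK119ub (32.6 points, 0.0199), immune genes (18.0 points, 0.159) and Polycomb genes (17.3 points, 0.0642) no longer did, and neither did the class of olfactory receptors (26.2 points, 0.137).

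With a window of 0 bp, H2AK119ub passed for suprabasal (23.6 points, 0.0258), fibroblast (26.7 points, 0.0242) and endothelial genes (32.9 points, 0.0117), and was lost for Polycomb genes (6.06 points, 0.564). H3K27me3 was lost for immune genes (11.4 points, 0.248), as was the class of melanocyte genes (26.9 points, 0.0932). With a window of 5 kb, H3K27me3 was lost for melanocyte genes (19.0 points, 0.0867) and their class was lost too (20.2 points, 0.161). H2AK119ub was lost for immune genes (22.5 points, 0.0546). Ribosomal protein genes turned from fewer to more H2AK119ub than other genes (11.5 points, 0.0438). H3K27me3 now differed for housekeeping (-23.0 points, 0.0155) and protocadherin genes (-13.5 points, 0.0438), as did the classes of endothelial (36.3 points, 0.0240) and housekeeping genes (-30.6 points, 0.0240).

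By locus, H3K27me3 was lost for melanocyte (20.004 points, 0.0843), immune (8.78 points, 0.520), endothelial (22.9 points, 0.0843) and solute carrier genes (4.38 points, 0.160), and H2AK119ub for immune genes (24.3 points, 0.0843). H2AK119ub passed for suprabasal (29.9 points, 0.0275), fibroblast (26.6 points, 0.0382) and endothelial genes (28.9 points, 0.0409), and H3K27me3 for housekeeping genes (-22.1 points, 0.0275).

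On the autosomes alone, H3K27me3 passed for housekeeping genes (-22.2 points, 0.00817), since their marked members Hprt and Pgk1 are on X, and so did the classes of pigmentation factors (26.7 points, 0.0294), endothelial (31.0 points, 0.0346), housekeeping (-33.4 points, 0.0169) and keratin genes (18.8 points, 0.0187). With the gene body, H2AK119ub passed for endothelial genes (27.7 points, 0.0357). For protocadherin genes the H2AK119ub call was lost (0.80 points, adjusted p = 1, exact test), H3K27me3 turned to 27.1 points (4.99e-05), and their class passed (49.3 points, 2.14e-08). The class of melanocyte genes was lost (19.4 points, 0.169).

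With a mark required at both ends, 1776 genes had both marks and 444 had H3K27me3 alone, as the stricter rule marks fewer genes. H3K27me3 was lost for pigmentation factors (2.78 points, 0.854), fibroblast (13.6 points, 0.0915), immune (8.79 points, 0.379) and ribosomal protein genes (-5.46 points, 0.212), also for solute carriers (-0.10 points, adjusted p = 1, exact test), and passed for protocadherin genes (-10.3 points, 0.00754). H2AK119ub passed for suprabasal (31.3 points, 0.00328) and endothelial genes (36.5 points, 0.00707) and was lost for Polycomb genes (7.54 points, 0.506). The classes of melanocyte genes (31.5 points, 0.108), ligands (9.32 points, 0.383) and ribosomal protein genes (-9.27 points, 0.465) were lost.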

Other observations

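The tests of a chromosome-wide gain on X and of accessible promoters, the sign tests at equal covered length, the gene body setting and the both-ends setting were chosen after the results they concern had been seen.

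Genes for the Polycomb machinery itself carried H2AK119ub more often than other genes, at 29 of 36 (80.6%, adjusted p = 0.00706), and H3K27me3 about as often, at 10 of 36 (27.8%, adjusted p = 0.736), by the same two-sided Fisher's exact test. Cbx2 (301 kb), Rybp (159 kb), Cbx7 (57.5 kb) and Pcgf2 (45.7 kb), which encode PRC1 subunits, had the widest regions with H2AK119ub alone. Rbbp7 on X (36.8 kb), Cbx8 (34.5 kb), Bmi1 (22.2 kb) and Scmh1 (21.9 kb) had the widest H3K27me3 regions together with H2AK119ub. The PRC2 core genes Ezh2, Eed and Suz12 were among the 7 genes with neither mark at their ends. The H2AK119ub call was lost in 4 alternative settings.

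H3K27me3 was found at few of the genes that are active in every cell. It was present at 2 of 25 housekeeping genes (adjusted p = 0.0850, Fisher's exact test), Hprt and Pgk1, both on X, and at 8 of 83 cytosolic ribosomal protein genes (9.64%, adjusted p = 0.00177), a call lost with a mark required at both ends (adjusted p = 0.212). H2AK119ub was found at 15 of the 25 (adjusted p = 0.842) and at 45 of the 83 (adjusted p = 0.722, same exact test), with Actb and Gapdh among the former, named after their values were seen. With a window of 5 kb the ribosomal protein genes had more H2AK119ub than other genes (11.5 points, adjusted p = 0.0438, exact test). Olfactory receptor genes carried both marks less often than other genes, with H2AK119ub at 26 and H3K27me3 at 45 of 1106 genes (2.35% and 4.07%, against 60.01% and 25.8% of other genes), although these genes lie in clusters and are not independent. Counted by locus, the difference was -39.3 points for H2AK119ub (adjusted p = 2.10e-12) and -14.4 points for H3K27me3 (adjusted p = 0.00774), by Fisher's exact test. Protocadherin cluster genes had H2AK119ub at 5 of 57 (adjusted p = 2.62e-13) and H3K27me3 at 8 of 57 (adjusted p = 0.0869, exact test), but all 57 lie in neighbouring clusters on chromosome 18, where many share an annotated end, so they are not independent and cannot be tested by locus. When regions anywhere in the gene body counted, no difference in H2AK119ub was detected (0.80 points, adjusted p = 1) and H3K27me3 was more frequent than at other genes (27.1 points, adjusted p = 4.99e-05), by the same exact test. Solute carrier genes, a large family of membrane transporters, had H2AK119ub at 273 of 364 (75%, adjusted p = 5.77e-12) and H3K27me3 at 122 of 364 (33.5%, adjusted p = 0.000320) by the exact test, the latter lost by locus and with a mark required at both ends.

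H3K27me3 covered 58.7% of X and at most 10.1% of any autosome. A gain in called signal on X that is independent of the antibody was taken to raise both coverages alike. Coverage of X was 10.1 times that of the median autosome for H3K27me3 and 1.84 times for H2AK119ub, a ratio of 5.46, while the same ratio reached at most 1.30 for an autosome. The 2 lists thus differed more on X than on any autosome. Coverage depends on calling thresholds that are unknown for both marks, so an equal gain in signal could raise the 2 coverages unequally. The ratio therefore cannot decide on such a gain. A candidate explanation is the inactive X chromosome of female cells, on which 10 genes known to escape inactivation should have less H3K27me3. Their median share of gene body inside H3K27me3 regions was 67.4%, against 100% for 1245 other X genes (two-sided permutation p = 0.0619), with Xist, Kdm6a, Kdm5c and Eif2s3x under 1%, as were 260 of the other genes (20.9%), and 7 of the 10 below the median of X genes of similar length, and for H2AK119ub it was 93.7% against 88.5% (p = 0.828), so this stays open. The prediction counted a p of 0.05 or more against the explanation, which was too strict for 10 genes, since a missed threshold does not show that values are alike, and the sex of the mice is not in the labels.

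Basal epidermal genes carried H2AK119ub without H3K27me3 at 17 of 26, but so did 15 of 26 suprabasal genes, although the sort removed suprabasal cells, and 19 of 36 Polycomb genes, so the pattern is not confined to basal genes and may come from the lists. If H2AK119ub chromatin were pulled down at accessible promoters in general, housekeeping and ribosomal protein genes would carry it as often, and this stays open, since for H2AK119ub alone the shares of 47.2% and 65.4% were not separated (two-sided Fisher's exact p = 0.127), and the shares with any H2AK119ub, 60 of 108 (55.6%) against 84.6% of basal genes (p = 0.00682), were compared after they were known. The larger covered length of H2AK119ub stays open too, since the excess of basal over other genes with the 4637 widest regions, which cover as much as H3K27me3 (14 of 26 against 25.4%, Fisher's exact p = 0.00231), compares genes within 1 list, and with autosomal regions cut to equal length 8 basal genes had H2AK119ub alone and 3 H3K27me3 alone (exact sign test p = 0.227), against 10 and 1 with the cut over all chromosomes (p = 0.0117), where X, which holds no basal gene, adds to the H3K27me3 length. Random lists matched on the number of genes within 500 kb had H2AK119ub alone at 34.6% of genes in the median and at 53.8% at the upper bound of their central 95%, below the 65.4% of basal genes. Several basal genes share a region, the strength of expression was not analysed here, and a dependence on the width of active domains stays untested.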
